A study of Caenorhabditis elegans with 10 samples.

How the data were processed

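Total RNA from young adult Caenorhabditis elegans, a nematode of about a millimetre, was measured on Affymetrix whole-genome expression arrays, with 5 biological replicates of the gas-1(fc21) strain and 5 of the wild type, 1 array each. Per the labels' protocols, animals were synchronised by bleaching, fed OP50 bacteria, collected by an automated sorter gated on size as groups of 1000 living adults, and RNA was extracted with Trizol from 500 to 1000 of them. Biotinylated cRNA was prepared from 1 µg of total RNA, per the labels' protocols. The labels call the samples biological replicates and give each a number from 1 to 5, with no scan date or batch.

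The deposited values are on a log2 scale, which was inferred from their range, because the scale, scanner software, background correction, probe set summary and normalization are not given in the sources used here. Values reached 14.2 at most, and natural logarithms of that size would exceed what a 16-bit scanner records. The array medians of the deposited log2 values lay between 6.22 and 6.61, a range of 0.386, and the quartiles differed between arrays. The rule set beforehand asked for quantile normalization only above a range of 0.5, so the values were used as deposited. The deposited table held 22625 probe sets. The 77 Affymetrix control probe sets were left out of the tests, and no filter on dim probe sets was applied, which left 22548. The number of arrays, rather than a count of reads, limits the precision of array values.

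Gene names came from the platform annotation supplied with the value table, updated through gene identifiers in the RefSeq gene table of assembly WBcel235. Of the tested probe sets, 20766 had 1 gene, 887 several and 895 none listed here, and 20701 of those with 1 gene matched the RefSeq table. No gene was named from a probe set with several. No coordinates are given, because the build behind the array is not given in the sources used here.

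Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, 2-sided), with genotype as the only term over all 10 arrays, and p-values were adjusted by the Benjamini-Hochberg method. A probe set was called at an adjusted p under 0.05. Differences are mutant minus wild type on the log2 scale, with the standard error (SE) from limma, and a fold is 2 raised to that difference. Exact 2-sided permutation tests used all 252 assignments of the 10 arrays, and 0.00794 is the smallest p they can give. No 2 arrays were duplicates, since at least 99.7% of probe sets differed in value between any pair.

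Of 38 gene lists written before the data were examined, 37 had at least 5 measured genes. They were tested with camera, which compares a list with all other genes, at its preset inter-gene correlation of 0.01, on 1 probe set for each of 17138 genes (the brightest on average among those naming 1 gene). List p-values were adjusted over the 37 lists, and counts of members use adjusted p-values over all probe sets unless given as adjusted over the list alone. The list of transcripts encoded by mitochondrial DNA matched 0 genes under its fixed names, and the reference calls those genes by other symbols. Every list test was repeated with a correlation estimated from the data and with fry, which asks whether the genes of a list move one way on balance.

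The genes named were chosen by a rule fixed beforehand. It takes gas-1, then the 8 largest rises and 8 largest falls among called probe sets with 1 gene and no overlap between groups. For a list past its test it takes up to 4 called members with the largest change, at least 1 per direction where both had called members, and for any other list the called member with the largest change in each direction. Near-identical families may be given as a family. Some named genes were read on probe sets whose suffix marks shared probes, which is not repeated for each gene.

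Both steps were tested on simulated data. For the mutant and wild-type comparison over 22548 probe sets, 32% of simulated changes of 0.5 on the log2 scale were recovered, 76% of changes of 1, 96% of changes of 2 and 100% of changes of 3, with 50 changed probe sets of each size. In the same simulation 8 of the 160 called probe sets were unchanged ones, and 0 were called where nothing changed. For the list test over 17138 genes, 60 of 60 lists shifted by 0.5 were called and 0 of 680 unchanged lists, with genes simulated as independent of each other. Probe sets were independent in the first simulation too. Neither simulation therefore shows how the tests behave where genes move together, as in the complex I list with its estimated correlation of 0.744.

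Alternatives fixed beforehand were quantile normalization, centring on array medians, leaving out the dimmest 33% or 50% of probe sets, an intensity trend with robust hyperparameters, array weights, the replicate number as a block, each array left out in turn, the mean of all probe sets of a gene, genes in place of probe sets, and leaving out probe sets whose suffix marks shared probes. A larger offset was planned for linear values only and was not run. Alternatives chosen after seeing the data left out wild-type replicates 1 and 5, or mutant replicates 4 and 5, or all 4, or used the mean of the sperm genes on each array as a covariate. For the mean of the respiratory chain and TCA cycle genes, single tissue lists were also used as covariates, neighbouring genes were also counted outside their largest run, and the share of mutant signal on wild-type replicate 5 was also taken over genes chosen without that array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.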

Results

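Whole young adult worms carrying gas-1(fc21) were compared with wild-type worms to find the metabolic pathways that change downstream of a defect in the mitochondrial electron transport chain. The gene gas-1 encodes a core subunit of complex I, the NADH dehydrogenase that passes electrons into the respiratory chain, and fc21 is a missense allele. Each group had 5 biological replicates on 1 array each, and 22548 probe sets for 17138 named genes were tested. Values are log2 intensities as deposited, and array medians were between 6.22 and 6.61. Pearson correlations across probe sets, which are not independent replicates, were 0.977 to 0.995 between mutant arrays, 0.954 to 0.996 between wild-type arrays and 0.946 to 0.982 between the groups.

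The transcript of gas-1 itself was higher in the mutant on both of its probe sets. The brighter probe set was at 11.11 ± 0.21 in the mutant and 10.44 ± 0.19 in the wild type (SD, n = 5), a difference of 0.67 (SE 0.12, 1.59-fold, limma adjusted p = 0.00567, exact permutation p = 0.00794). The dimmer probe set was at 10.38 ± 0.26 and 9.67 ± 0.24 (SD, n = 5), a difference of 0.72 (SE 0.15, 1.64-fold, limma adjusted p = 0.0108, exact permutation p = 0.00794). Every mutant array lay above every wild-type array on both. Because fc21 is a missense allele, a transcript level does not check the genotype labels. Both gas-1 probe sets have the suffix that marks shared probes, so a contribution from another transcript is not excluded.

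**Figure D1:**
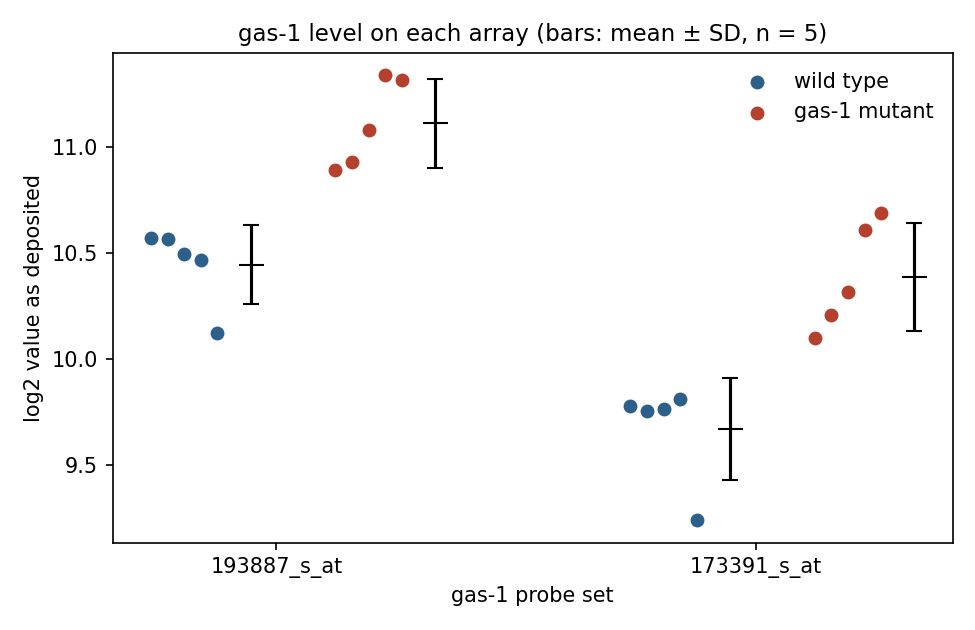
Deposited log2 values (vertical axis) of both gas-1 probe sets (horizontal axis) on each of the 5 wild-type and 5 mutant arrays, 1 point per array, with black bars for mean ± SD. The mutant means of 11.11 and 10.38 lie above the wild-type means of 10.44 and 9.67, with no overlap between groups.

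Across the genome, transcripts rose and fell in the mutant, with more rises than falls over all 10 arrays. Of the 22548 probe sets, 1701 rose and 964 fell at an adjusted p under 0.05, 19883 did not pass, and 447 rose and 172 fell at least 2-fold. The groups did not overlap on 2919 probe sets, or 12.9%, where chance gives 0.794%. The number of falls depended on single arrays: 1609 probe sets fell without wild-type replicate 5, and 479, 493 and 480 fell without wild-type replicates 2, 3 and 4 in turn. The balance turned without the 4 arrays that stood apart (wild-type replicates 1 and 5, mutant replicates 4 and 5, chosen after seeing the data), with 2317 rises and 2522 falls, 403 and 484 of them at least 2-fold.

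The 8 largest rises included 3 nspe genes, a cytochrome P450 and a flavin-containing monooxygenase. The nspe genes form a family of small nematode-specific peptides. Transcript of nspe-1 rose from 4.38 ± 0.31 to 9.82 ± 0.12 (SD, n = 5), a 43.5-fold difference (log2 5.44, SE 0.14, limma adjusted p = 3.07e-08), and nspe-3 and nspe-7 rose 20.2-fold and 15.6-fold on probe sets that may share probes within the family. The cytochrome P450 gene cyp-33C8 rose 32.8-fold (5.03, SE 0.19, adjusted p = 2.28e-07) and the flavin-containing monooxygenase gene fmo-2 rose 29.1-fold (4.86, SE 0.31, adjusted p = 6.26e-06). The other genes of this set were F41C3.1 at 29.3-fold, Y49G5A.1 at 24.8-fold and F57G8.7 at 20.2-fold. For 6 of the 8 genes, nspe-1, nspe-3, nspe-7, F41C3.1, fmo-2 and F57G8.7, the wild-type mean (4.2 to 4.8) was within or below the range of the background control medians. These were 4.43 to 4.75 on wild-type replicates 2 to 5 and 5.25 on wild-type replicate 1. The mean of F57G8.7 (4.80) was below that of replicate 1 only. The folds of the 6 genes are therefore lower bounds, for F57G8.7 only possibly so, and their order is not settled.

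The largest fall was in fat-7, a stearoyl-CoA desaturase that makes monounsaturated fatty acids. It went from 11.15 ± 0.47 in the wild type to 7.25 ± 0.26 in the mutant (SD, n = 5), 15-fold lower (−3.91, SE 0.22, limma adjusted p = 2.47e-06). The lysozyme gene lys-4 was 7.10-fold lower (−2.83, SE 0.19, adjusted p = 9.72e-06), the UDP-glucuronosyltransferase gene ugt-41 was 5.84-fold lower (−2.55, SE 0.36, adjusted p = 0.00132), and the C-type lectin gene clec-47 was 5.82-fold lower (−2.54, SE 0.22, adjusted p = 4.51e-05). The remaining 4 were C30G12.2 at 10.9-fold lower, T22B7.7 at 7.91-fold, F23F12.12 at 7.51-fold and F42A10.7 at 5.52-fold. The probe sets of lys-4, T22B7.7 and F23F12.12 have suffixes that mark shared probes.

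**Figure D2:**
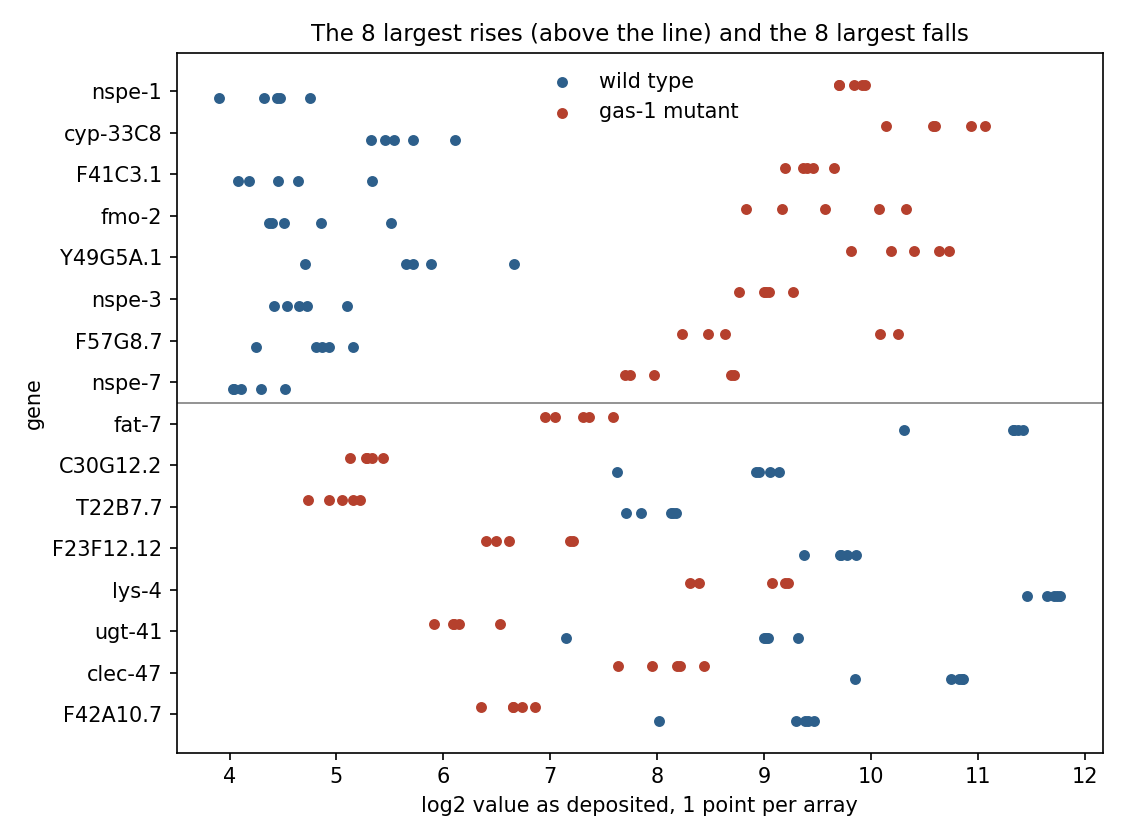
Deposited log2 values (horizontal axis) of the 8 genes with the largest rise and the 8 with the largest fall (vertical axis), 1 point per array, 5 arrays per group. The groups are apart for all 16 genes, from nspe-1 with means of 9.82 and 4.38 to fat-7 with means of 7.25 and 11.15.

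Nuclear genes of the respiratory chain were higher in the mutant in small steps that most members shared. Of 27 subunits of complex I other than gas-1, 13 rose, 0 fell and 14 did not pass (19 rose adjusted over the list alone), and 26 of the 27 had a positive difference. The subunit genes nduf-7 (0.54, SE 0.08, 1.46-fold), nuo-5 (0.53, SE 0.10, 1.44-fold), nduf-9 (0.48, SE 0.09, 1.4-fold) and nuo-2 (0.48, SE 0.09, 1.39-fold) rose most. All 4 were on probe sets whose suffix marks shared probes. The complex I list was past the camera test (adjusted p = 1.59e-09), and its array mean was 11.35 ± 0.15 in the mutant and 11.03 ± 0.08 in the wild type (SD, n = 5, exact permutation p = 0.00794). With an estimated correlation of 0.744 the call was lost, at adjusted p = 0.491 with an estimated correlation. For complexes II to V, 16 of 36 genes rose and 0 fell (25 and 0 adjusted over the list alone), led by ucr-2.1 of complex III (0.75, SE 0.15, 1.68-fold), R07E4.3 (0.53, SE 0.13, 1.44-fold), asg-2 (0.52, SE 0.10, 1.43-fold) and Y69A2AR.18, the gamma subunit of ATP synthase (0.48, SE 0.06, 1.39-fold). That list was also past camera (adjusted p = 1.12e-09) and lost its call, at adjusted p = 0.491 with an estimated correlation. Without the 4 arrays that stood apart, both camera calls held, with medians of 0.185 in place of 0.338 for complex I and 0.15 in place of 0.27 for complexes II to V.

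The pyruvate dehydrogenase and TCA cycle list had 10 of 19 genes that rose and 1 that fell (11 and 2 adjusted over the list alone). Aconitase aco-2 (0.77, SE 0.10, 1.70-fold), the isocitrate dehydrogenase subunit gene idhg-2 (0.69, SE 0.20, 1.62-fold) and dihydrolipoamide dehydrogenase dld-1 (0.61, SE 0.14, 1.52-fold) rose. The gene that fell was sucg-1, a succinyl-CoA ligase subunit (−0.28, SE 0.06, 1.21-fold lower). Camera gave adjusted p = 0.00047 for the list, against adjusted p = 0.676 with an estimated correlation and 0.0698 without the 4 arrays that stood apart. A permutation of its array means gave exact p = 0.03175 (0.0653 adjusted over the lists). The groups overlapped, with mutant replicate 1 at 10.607 and wild-type replicates 2 to 4 at 10.612 to 10.627.

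Some genes of carbohydrate enzymes rose as well. In glycolysis, 8 of 16 genes rose and 0 fell (13 and 1 adjusted over the list alone). The aldolase gene aldo-1 rose 3.25-fold (1.70, SE 0.18), lactate dehydrogenase ldh-1 1.67-fold (0.74, SE 0.13), and the near-identical glyceraldehyde-3-phosphate dehydrogenase genes gpd-3 and gpd-2 rose 1.49-fold and 1.44-fold on probe sets that may share probes. The list was past camera (adjusted p = 4.85e-06) and not with the other setting (adjusted p = 0.491 with an estimated correlation). Among the 6 genes of the glyoxylate shunt and gluconeogenesis, 4 rose and 0 fell (5 and 0 adjusted over the list alone). The phosphoenolpyruvate carboxykinase gene pck-1 rose 3.69-fold (1.88, SE 0.16), the glyoxylate enzyme gene icl-1 3.54-fold (1.82, SE 0.17), pck-2 1.53-fold (0.61, SE 0.08) and pyruvate carboxylase pyc-1 1.38-fold (0.47, SE 0.12). Camera gave adjusted p = 2.03e-05 for this list, and adjusted p = 0.491 with an estimated correlation.

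Fatty acid genes moved in both directions. For mitochondrial oxidation, 7 of 26 genes rose and 2 fell (9 and 2 adjusted over the list alone). The acyl-CoA synthetase gene acs-2 rose 10.6-fold (3.40, SE 0.33), the carnitine palmitoyltransferase gene cpt-4 3.22-fold (1.69, SE 0.26) and the acyl-CoA dehydrogenase gene acdh-9 2.29-fold (1.19, SE 0.11), while acdh-8 was 3.25-fold lower (−1.70, SE 0.40). Camera called the list (adjusted p = 0.0358), with adjusted p = 0.491 with an estimated correlation, and the call also ended without wild-type replicate 5 (adjusted p = 0.105), 1 (0.0801) or mutant replicate 2 (0.0529), under centring (0.0513) and array weights (0.0808), without the dimmest 33% of probe sets (0.0563), and without the 4 arrays that stood apart (0.266). In peroxisomal oxidation 4 of 12 genes rose, ech-8 most (1.31, SE 0.22), and 2 fell, the acyl-CoA oxidase gene acox-1.2 most (−1.56, SE 0.15). The counts for that list were 5 and 2 adjusted over the list alone, and it was not past camera as deposited (adjusted p = 0.0562). It was called higher under quantile normalization (adjusted p = 0.0267), centring (0.0115), the replicate block (0.0491) and without the dimmest 50% of probe sets (0.0488), and without mutant replicates 1, 2 or 3 (0.029, 0.0384 and 0.0206) or wild-type replicates 2 or 4 (0.0489 and 0.0449), but not without the 4 arrays that stood apart (0.482). Among synthesis, elongation and desaturation genes, 5 of 20 rose, the elongase gene elo-4 most (0.96, SE 0.16), and 2 fell, fat-7 among them. Those counts were again 5 and 2 adjusted over the list alone (camera adjusted p = 0.784). Of 17 lipases and fatty acid binding genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone), the lipase gene lipl-1 most (1.94, SE 0.34, camera adjusted p = 0.124).

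In the breakdown of propionate and branched-chain amino acids, 3 of 13 genes rose and 1 fell (7 and 1 adjusted over the list alone). The aminotransferase gene bcat-1 rose 1.75-fold (0.81, SE 0.09), methylmalonyl-CoA mutase mmcm-1 1.36-fold (0.44, SE 0.11) and dbt-1 of the branched-chain keto acid dehydrogenase 1.22-fold (0.29, SE 0.07), and hach-1 was 1.45-fold lower (−0.54, SE 0.12). The list was past camera (adjusted p = 0.00656), with adjusted p = 0.491 with an estimated correlation and 0.0839 without the 4 arrays that stood apart. One-carbon and methionine genes were split, with 4 of 15 that rose and 4 that fell (5 and 8 adjusted over the list alone). The cystathionine beta-synthase gene cbs-1 rose 2.47-fold (1.3, SE 0.29) and methionine synthase metr-1 was 1.79-fold lower (−0.84, SE 0.09), and that list was not past camera (adjusted p = 0.239).

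Mitochondrial chaperones and proteases had 6 of 17 genes that rose and 0 that fell (8 and 0 adjusted over the list alone). The import gene timm-23 (0.66, SE 0.14, 1.58-fold), the proteases ymel-1 (0.58, SE 0.08, 1.5-fold) and clpp-1 (0.53, SE 0.07, 1.45-fold) and the co-chaperone dnj-10 (0.55, SE 0.08, 1.47-fold) rose most. Camera gave adjusted p = 0.000598, adjusted p = 0.491 with an estimated correlation and 0.0733 without the 4 arrays that stood apart. Chaperones of other compartments did not pass as lists over all arrays. Of 16 genes for ER stress and folding, 0 rose and 2 fell, pdi-2 most (−0.66, SE 0.18), with counts of 1 and 3 adjusted over the list alone (camera adjusted p = 0.142). Without mutant replicate 4 or 5 that list passed as lower (adjusted p = 0.041 and 0.0247), and without both its median was −0.215 in place of −0.09 (adjusted p = 0.000149). Of 15 cytosolic heat shock genes, hsp-43 rose (0.71, SE 0.06), with counts of 1 and 1 adjusted over the list alone (camera adjusted p = 0.73). The other called probe set, hsp-12.6, had means of 4.21 in the mutant and 4.67 in the wild type (difference −0.46, SE 0.13), both at the level of the background controls, so it is not read as a change of the gene.

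Antioxidant enzymes had 9 of 24 genes that rose and 0 that fell (10 and 2 adjusted over the list alone). The thioredoxin reductases trxr-2 (1.00, SE 0.09, 2-fold) and trxr-1 (0.92, SE 0.13, 1.90-fold), the glutathione peroxidase gene gpx-6 (0.97, SE 0.17, 1.96-fold) and the mitochondrial superoxide dismutase gene sod-3 (0.91, SE 0.13, 1.88-fold) rose most. Camera called the list (adjusted p = 0.00419), with adjusted p = 0.491 with an estimated correlation and 0.0525 without the 4 arrays that stood apart. The wild-type mean of gpx-6 (5.21) was below the background control median of wild-type replicate 1 (5.25) only. It was above those of wild-type replicates 2 to 5 (4.43 to 4.75), so its fold may be a lower bound. Of the 5 measured targets of the hypoxia factor HIF-1, 3 rose and 0 fell, and all 5 rose adjusted over the list alone. The 3 were nhr-57 (1.15, SE 0.23, 2.22-fold), cysl-2 (1.08, SE 0.18, 2.11-fold) and rhy-1 (0.64, SE 0.10, 1.56-fold). Camera gave adjusted p = 0.00038 for the HIF-1 list, and adjusted p = 0.491 with an estimated correlation. Targets of the insulin-pathway factor DAF-16 were split, with 2 of 13 that rose, icl-1 most, and 3 that fell, the lysozyme gene lys-7 most (−1.84, SE 0.22). The counts were 2 and 3 adjusted over the list alone, and the list was not past camera (adjusted p = 0.73).

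Detoxification genes included several large changes. Of 45 glutathione S-transferases 15 rose and 0 fell (18 and 0 adjusted over the list alone), and 7 of the 45 were at least 2-fold higher in mean. The genes gst-14 (3.73, SE 0.28, 13.3-fold), gst-13 (2.45, SE 0.08, 5.46-fold), gst-4 (2.18, SE 0.29, 4.52-fold) and gst-6 (1.73, SE 0.26, 3.32-fold) rose most. The wild-type mean of gst-14 (4.5) was not above the background controls, so 13.3-fold is a lower bound. The list was past camera (adjusted p = 1.72e-06), with adjusted p = 0.491 with an estimated correlation. Of 73 cytochrome P450 genes 17 rose, cyp-33C8 most, and 6 fell, cyp-35A3 most (−2.37, SE 0.10, 5.17-fold lower), with counts of 19 and 7 adjusted over the list alone. Of 64 UDP-glucuronosyltransferases 15 rose, ugt-19 most (3.32, SE 0.23, 9.99-fold), and 11 fell, ugt-41 most, with counts of 17 and 12 adjusted over the list alone. Neither family was past camera (adjusted p = 0.136 and 0.216), and both were past fry (adjusted p = 0.00779 and 0.0087). Fry tests the balance within a list and does not compare it with other genes. The P450 genes were split, 42 higher and 31 lower in mean, as were the UDP-glucuronosyltransferases, 34 higher and 30 lower. The P450 list was past camera under centring (adjusted p = 0.0491) and without mutant replicates 4 and 5 (0.0313). Of the 16 lists that camera called, 13 were past fry and the sperm, collagen and muscle lists were not.

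Genes of pathogen defence went both ways. Of 60 lysozymes and antimicrobial peptides 8 rose, the peptide gene abf-2 most (2.38, SE 0.20, 5.20-fold), and 7 fell, lys-4 most. The counts were 8 and 9 adjusted over the list alone (camera adjusted p = 0.463). The wild-type mean of abf-2 (4.92) was below the background control median of wild-type replicate 1 (5.25) only, so its fold may be a lower bound. Of 220 C-type lectins 11 rose, clec-4 most (2.90, SE 0.32, 7.48-fold), and 13 fell, clec-47 most, with counts of 10 and 12 adjusted over the list alone (camera adjusted p = 0.216).

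Sperm genes made up the strongest decrease of any list, and they varied most between replicates. Of 70 genes 12 fell and 1 rose (46 and 1 adjusted over the list alone), and 40 were at least 2-fold lower in mean. The nspd genes, another family of nematode-specific peptides, fell, nspd-4 by 9.68-fold (−3.28, SE 0.92) and nspd-7 by 6.38-fold (−2.67, SE 0.74), on probe sets that may share probes, and ssp-19 was 3.78-fold lower (−1.92, SE 0.53). The groups overlapped for each of these genes. Wild-type replicate 5 lay far below the other wild-type arrays, by −3.29 (nspd-4), −3.11 (nspd-7) and −2.49 (ssp-19), so these folds depend on it. The gene that rose was spe-5 (0.49, SE 0.08, 1.4-fold), which encodes a subunit of the vacuolar ATPase. Camera called the list (adjusted p = 1.12e-09), with adjusted p = 0.491 with an estimated correlation. Its array means were 7.21 ± 0.88 in the mutant and 8.65 ± 0.77 in the wild type (SD, n = 5), a permutation of these means gave exact p = 0.0556, and fry gave adjusted p = 0.0558. Without the 4 arrays that stood apart, chosen after seeing the data, the list median was −2.64 in place of −1.70 (camera adjusted p = 9.56e-33). Among those arrays, wild-type replicate 5 and mutant replicates 4 and 5 lay toward the other group in sperm genes. Leaving them out widens the difference by construction, so that p adds no evidence. Wild-type replicates 1 to 4 were at 8.97 to 9.02 and wild-type replicate 5 at 7.28, while mutant replicates 1 to 3 were at 6.53 to 6.60 and mutant replicates 4 and 5 at 8.19 and 8.16.

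Over all arrays, other germline groups differed less. Of 20 oocyte and eggshell genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.983, direction down, with a median of 0.01 and a mean of 0.02). Wild-type replicate 5 had the highest mean of this list at 12.19. Fits chosen after seeing the data called it in opposite directions, higher without the 4 arrays that stood apart (median 0.159, adjusted p = 0.00565) and lower with the sperm mean as a covariate (median −0.199, adjusted p = 1.51e-06). Of 24 genes of germline proliferation and meiosis 4 fell and 0 rose (4 and 0 adjusted over the list alone). They were the helicase gene glh-1 (−0.44, SE 0.07, 1.35-fold lower), msh-5 (−0.42, SE 0.07) and the synaptonemal complex genes syp-2 (−0.30, SE 0.06) and syp-3 (−0.29, SE 0.08). That list was past camera (adjusted p = 0.01), with adjusted p = 0.668 with an estimated correlation, and its call ended without wild-type replicate 5 (adjusted p = 0.125), without mutant replicates 4 and 5 (0.103) and without the 4 arrays that stood apart (0.438). Of 5 vitellogenins, the yolk proteins, 0 passed by either adjustment, including the one adjusted over the list alone (camera adjusted p = 0.358). Of 14 regulators of embryonic lineages tbx-2 rose (0.50, SE 0.14), 0 fell and 0 passed adjusted over the list alone (camera adjusted p = 0.0809, 0.042 under centring, 0.0292 without wild-type replicates 1 and 5, and 0.0399 by fry).

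Body tissue lists followed the same uneven replicates. Of 146 cuticle collagens 4 rose and 0 fell (3 and 0 adjusted over the list alone), dpy-17 by 2.63-fold (1.4, SE 0.40), col-101 by 1.54-fold (0.62, SE 0.10), col-76 by 1.36-fold (0.44, SE 0.09) and col-95 by 1.34-fold (0.42, SE 0.07). The list was past camera (adjusted p = 0.00434), with adjusted p = 0.83 with an estimated correlation and fry adjusted p = 0.442. Its means were 9.12 and 9.07 on mutant replicates 4 and 5 and 7.82 on wild-type replicate 5, while mutant replicates 1 to 3 (8.21 to 8.27) lay below wild-type replicates 1 to 4 (8.30 to 8.72). The call ended without wild-type replicate 5 (adjusted p = 0.124), mutant replicate 4 (0.0894) or mutant replicate 5 (0.0605), and without both mutant arrays the median was −0.027, whereas with the sperm mean as a covariate it was 0.788 (adjusted p = 1.00e-20). The sperm mean itself differed between groups (−1.44), so that fit extrapolates between them and its p is not strong evidence of a rise. Of 20 muscle markers, the tropomyosin gene lev-11 (0.56, SE 0.12, 1.48-fold) and the myosin light chain gene mlc-3 (0.50, SE 0.13, 1.42-fold) rose and 0 fell (3 and 0 adjusted over the list alone). The muscle list was past camera (adjusted p = 0.0319), with adjusted p = 0.83 with an estimated correlation and fry adjusted p = 0.354. Its means were 11.10 and 11.06 on mutant replicates 4 and 5 and 10.01 on wild-type replicate 5, while mutant replicates 1 to 3 (10.44 to 10.54) lay below wild-type replicates 1 to 4 (10.60 to 10.72). The call ended without wild-type replicate 5 (adjusted p = 0.166), wild-type replicate 1 (0.0645), mutant replicate 4 (0.145) or mutant replicate 5 (0.118), and the median was −0.092 without the 4 arrays that stood apart, whereas with the sperm mean as a covariate it was 0.849 (adjusted p = 8.06e-12).

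Markers of other tissues did not pass as lists over all arrays. Of 19 neuron markers the synaptobrevin gene snb-1 rose (0.34, SE 0.08), 0 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.216). Of 11 pharynx markers 0 passed, also adjusted over the list alone (camera adjusted p = 0.298), but the list was called lower without the 4 arrays that stood apart (adjusted p = 0.00596, median −0.216 in place of −0.062). Of 12 intestine markers vha-6 rose (0.55, SE 0.14), 2 fell, the protease gene cpr-1 most (−1.37, SE 0.15, 2.58-fold lower), and the counts were 1 and 3 adjusted over the list alone. The intestine list had a median of 0.02, a mean of −0.08 and a camera direction of down (adjusted p = 0.486). Fits chosen after seeing the data called it in opposite directions, lower without the 4 arrays that stood apart (median −0.26, adjusted p = 0.0048) and higher with the sperm mean as a covariate (median 0.49, adjusted p = 0.0335).

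**Figure D3:**
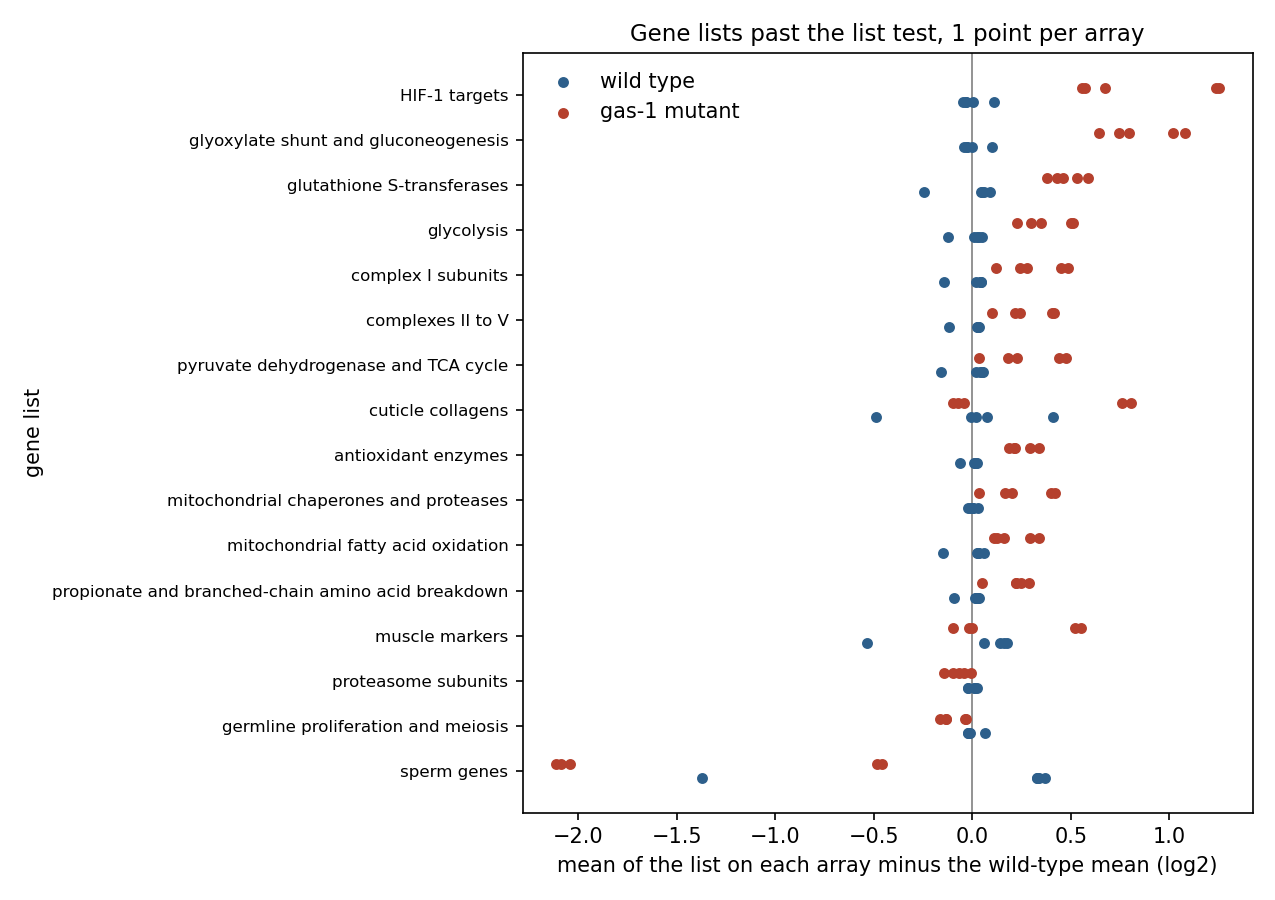
Mean of each gene list on each array minus the wild-type mean (horizontal axis, log2) for the 16 lists past the camera test (vertical axis), 1 point per array, 5 arrays per group. Mutant arrays lie above all wild-type arrays for complex I and glycolysis, whereas the sperm, collagen and muscle lists spread widely within groups.

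**Figure D4:**
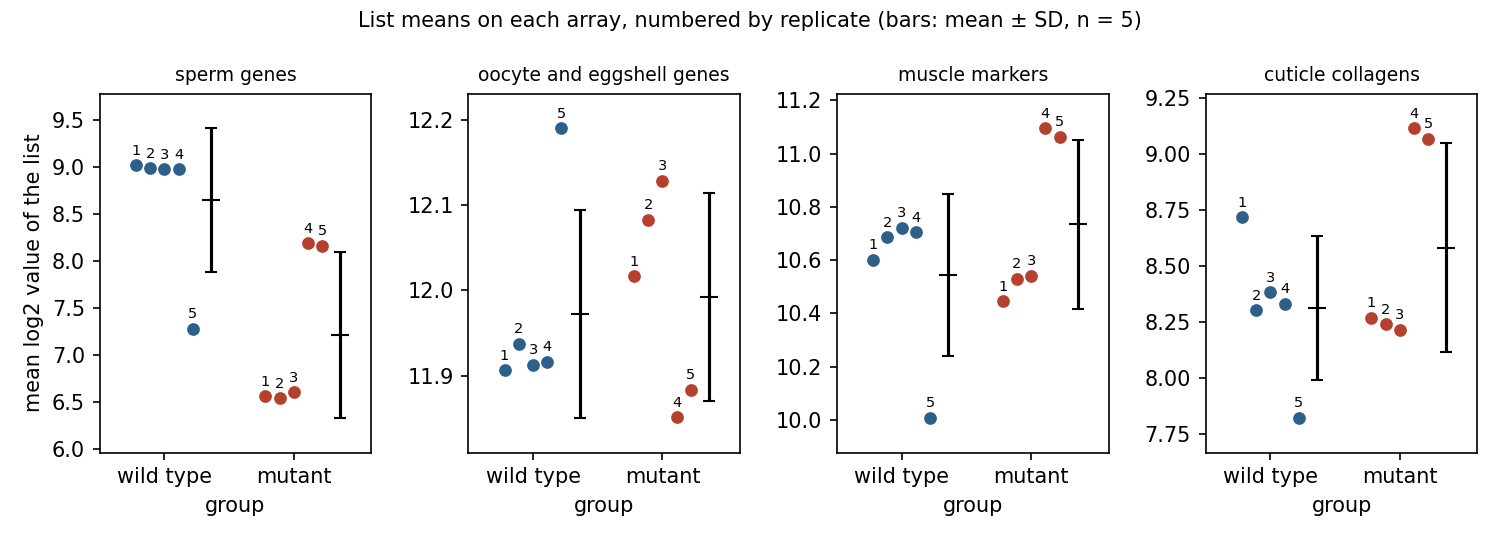
Mean log2 value (vertical axes, a separate scale per panel) of the sperm, oocyte and eggshell, muscle and cuticle collagen lists on each array, numbered by replicate, with bars for mean ± SD (n = 5). Wild-type replicate 5, with a sperm mean of 7.28, lies outside the other wild-type arrays in all 4 panels, and mutant replicates 4 and 5 stand apart from mutant replicates 1 to 3.

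Lists of protein synthesis and turnover held few changed genes. Of 75 cytosolic ribosomal proteins 0 passed, also adjusted over the list alone (camera adjusted p = 0.245). Of 59 mitochondrial ribosomal proteins 2 fell and 0 rose, mrps-23 most (−0.40, SE 0.09), with the same 2 and 0 adjusted over the list alone (camera adjusted p = 0.0886). That list was called lower under quantile normalization (adjusted p = 0.0289), centring (0.042) and array weights (0.00325), without mutant replicate 4 (0.0161), mutant replicate 5 (0.0199) or wild-type replicate 5 (0.0419), and without the 4 arrays that stood apart (0.000431, median −0.135 in place of −0.06). Of 33 proteasome subunits rpn-12 fell (−0.24, SE 0.06, 1.18-fold lower), 0 rose and 0 passed adjusted over the list alone, while 30 of the 33 had a negative difference. The proteasome list was past camera (adjusted p = 0.00514), with adjusted p = 0.683 with an estimated correlation, and its call ended without wild-type replicate 5 (adjusted p = 0.0563) and without the 4 arrays that stood apart (0.154). Of 18 vacuolar ATPase subunits vha-6 rose and 0 fell, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.276). Of 19 genes of autophagy and mitophagy 2 rose, the adaptor gene sqst-1 most (1.33, SE 0.21, 2.52-fold), and 0 fell, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.376). With array weights 5 of the 16 camera calls were lost, for mitochondrial fatty acid oxidation and for collagens (adjusted p = 0.315), germline proliferation (0.209), muscle (0.755) and proteasome (0.0736). In all, camera called 13 lists higher and 3 lower in the mutant at its preset correlation and 0 in either direction with an estimated correlation, where 0 of the 16 calls held. Without the 4 arrays that stood apart 7 of the 16 held, 9 were lost and 6 other lists were called: cytochrome P450s and oocyte genes higher, and ER stress, mitochondrial ribosomal, pharynx and intestine genes lower. Among calls that held there, medians were smaller for glycolysis (0.215 in place of 0.369), HIF-1 targets (0.622 in place of 0.974) and glutathione S-transferases (0.161 in place of 0.246). Of 100 divisions of the 10 arrays into groups of 5, the real one included, 16 called as many lists at the preset correlation. A permutation of array means, which ignores all other genes, gave exact p = 0.00794 (0.021 adjusted over the lists) for several lists. They were complex I, complexes II to V, glycolysis, glyoxylate shunt, both fatty acid oxidation lists, propionate breakdown, mitochondrial chaperones, antioxidants and HIF-1 targets. Glutathione S-transferases, P450s, UDP-glucuronosyltransferases and germline proliferation joined them. Called lists short of it were TCA cycle, sperm, collagen, muscle and proteasome.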

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

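The tests of scaling and of somatic tissue, and the other divisions of the arrays, were written before their results were seen; the tests of mutant animals, of the oocyte genes and of neighbouring genes were chosen after. Of these, 3 were redefined after a first version had been run: that of mutant animals first used 8 genes, that of linked strain variants first compared the genes around gas-1 with the rest of the X chromosome, and that of tandem families first counted every pair without a shared name prefix. By that first count 8 pairs were left, above the 4 that 95% of random placements stayed within (permutation p = 3e-04), which argued against tandem families. Of 264 groups of 5 arrays examined (list means and named genes), 60 held an array far from the other 4, where chance gives about 13.2 because the rule marks about 1 in 20 groups by chance, and 52 of the 60 were wild-type replicate 5. The rule looks for a single array, so arrays that stand apart as a pair mask each other. Mutant replicates 4 and 5 did so in sperm genes, at 8.19 and 8.16 against 6.53 to 6.60 on mutant replicates 1 to 3. The share of marks on wild-type replicate 5 depends partly on this, and the cause of the mutant split was not tested. Each value here is the marked array minus the mean of the other 4 of its group, on the log2 scale.

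Wild-type replicate 5 lay low for most of the lists concerned, by −0.18 for complex I subunits, −0.15 for complexes II to V, −0.20 for pyruvate dehydrogenase and TCA cycle, −0.15 for glycolysis, −0.19 for mitochondrial fatty acid oxidation, −0.12 for propionate and branched-chain amino acid breakdown, −0.43 for one-carbon and methionine metabolism, −0.0757 for antioxidant enzymes, −0.30 for glutathione S-transferases, −0.25 for UDP-glucuronosyltransferases, −1.71 for sperm genes, −0.59 for intestine markers, −0.67 for muscle markers, −0.37 for neuron markers, −0.16 for mitochondrial ribosomal proteins and −0.40 for vacuolar ATPase. It lay high by 0.12 for glyoxylate shunt and gluconeogenesis, 0.20 for ER stress and folding, 0.17 for cytosolic heat shock, 0.26 for vitellogenins, 0.27 for oocyte and eggshell genes and 0.0835 for germline proliferation and meiosis. Mutant replicate 1 was low for the propionate and branched-chain amino acid list, at −0.19.

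Among single genes, wild-type replicate 5 lay low for sperm genes, nspd-4 −3.29, nspd-7 −3.11 and ssp-19 −2.49, and for metabolic genes and others, fat-7 −1.05, C30G12.2 −1.39, ugt-41 −1.95, clec-47 −0.97, F42A10.7 −1.38, gas-1 −0.40, nuo-5 −0.29, nuo-2 −0.27, ucr-2.1 −0.56, asg-2 −0.38, ldh-1 −0.21, gpd-3 −0.29, gpd-2 −0.29, acdh-8 −1.95, acdh-9 −0.41, hach-1 −0.41, metr-1 −0.33, col-101 −0.49, col-95 −0.25, glh-1 −0.19, vha-6 −0.48 and mlc-3 −0.52. It lay high for icl-1 0.74, cbs-1 0.79, lys-7 1.17, spe-5 0.23 and sqst-1 0.77. On other arrays, wild-type replicate 1 was apart for cpt-4 −0.89, elo-4 −0.79 and gst-13 −0.26, mutant replicate 3 for elo-4 −0.32 and lipl-1 −0.78, and mutant replicate 5 for sucg-1 0.15 and dnj-10 0.29.

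Of the 77 control probe sets left out of the tests, 12 were higher in the mutant (limma, Benjamini-Hochberg over the controls). Only rises were looked for, so controls that may have been lower were not counted. Probe sets for worm glyceraldehyde-3-phosphate dehydrogenase were higher by 0.55, 0.74 and 0.63, those for catalase by 0.42 and 0.37, those for gly-14 by 1.21, 0.46 and 1.16, and 4 whose target is not given in the sources used here by 0.56, 0.52, 0.29 and 0.28.

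The first pattern is wild-type replicate 5, whose sperm genes were low. Array scaling does not account for it, since after quantile normalization its sperm mean was still −1.58 from the other 4 (log2). Mutant animals in that culture, or an exchanged label, are argued against by the 74 genes that rose at least 4-fold, which showed a median of 1.79% of the mutant signal there (upper quartile 7.54%), where the sperm genes would need 107%; since that array took part in choosing these genes, 87 genes were also chosen without it, after seeing the data, with a median of 2.81% (upper quartile 17.5%). Across all probe sets, however, wild-type replicate 5 correlated at 0.982 and 0.980 with mutant replicates 2 and 3, and at 0.954 to 0.979 with the other wild-type arrays. With mutant replicates 1, 4 and 5 it correlated at 0.977, 0.966 and 0.969. Whole-array similarity thus does not place it with the wild type, and the argument rests on the risen genes. The oocyte and eggshell mean of wild-type replicate 5 lay 0.25 above the highest of the other 4, whose whole range was 0.03, but this test was prompted by the same values and decides nothing. A later point between sperm and oocyte production and a larger share of germline against body tissue, with muscle at −0.67, intestine at −0.59 and neurons at −0.37 on that array, both stay open, as do culture and collection day, because the labels give no batch.

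The second pattern is the rise of respiratory chain and TCA cycle genes, whose 82 genes had a mean of 11.46 ± 0.15 in the mutant and 11.17 ± 0.08 in the wild type (SD, n = 5, exact permutation p = 0.00794). The pyruvate dehydrogenase and TCA cycle list alone overlapped between groups (exact permutation p = 0.03175). Scaling is argued against by a difference of 0.28 under quantile normalization against 0.29 as deposited. More somatic tissue is argued against as the whole source, though not as a part: with the mean of muscle, neuron and pharynx markers as a covariate the difference was 0.26 (SE 0.04), but that mean hardly differed between groups (0.05, exact permutation p = 0.77), because muscle (0.19) and pharynx (−0.18) cancelled, and with single lists, chosen after seeing the data, it was 0.22 (muscle), 0.20 (neuron), 0.37 (pharynx), 0.22 (collagens) and 0.48 (sperm), with SE of 0.03 to 0.06. Without the 4 arrays that stood apart the difference was 0.15 (SE 0.05), so these arrays carried part of it. That the rest is a response to the complex I defect stays a hypothesis, found and tested on the same arrays, and culture effects between the strains stay open.

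The third pattern is that genes changed at least 4-fold lay side by side: among 101 such genes, 15 pairs lay within 3 measured genes of each other in the order of assembly WBcel235, where 10000 random placements gave a median of 2 (permutation p = 1e-04, the smallest they can give). Of these pairs 9 came from a single run of 5 genes, nspe-3, nspe-1, Y38E10A.14, nspe-7 and nspe-5, and outside it, a count chosen after seeing the data, 6 pairs were left among 96 genes (random median 1, permutation p = 0.0071). Strain variants linked to gas-1 are argued against, since 0 of the 15 pairs lay among the 30 measured genes on either side of it, and variants elsewhere were not tested. Tandem families may account for part, since 0 of the 7 pairs in which both genes have a family name joined different families. However, 5 of the 7 were nspe pairs. Another is pmk-3 with pmk-2, which lie in an operon, so kinship and the operon cannot be told apart for it. Kinship stays open for the other 8 pairs, as do shared probes except for nspd-7 (−2.67) and Y43C5A.3 (2.35), which moved in opposite directions.

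For the count of changed probe sets, 1 of 100 divisions of the arrays, the real one, gave 2665 or more, and the highest of the others gave 445. A chance division of the arrays is argued against at a resolution of 1 in 100. In mixed divisions the group difference adds to the spread within groups, which lowers their counts. A culture or batch difference that follows genotype is not addressed by this test. For the list tests, 16 of 100 divisions called 16 lists or more and the highest called 22, so chance is not excluded for the number of lists. Some of these divisions, such as one that called 21, exchanged only 1 array per group with the real one and kept much of the genotype difference. Others, the one at 22 among them, were mixed more evenly. The 16 in 100 is therefore not a clean rate of chance calls.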

How the results depend on the processing

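The covariate and the joint exclusions of arrays were chosen after seeing the data. As reported, 1701 probe sets rose and 964 fell, 447 and 172 of them at least 2-fold, and 13 lists were called higher and 3 lower. Array weights gave 2969 rises, 2535 falls and 393 falls of at least 2-fold. Centring on array medians gave 290 falls of at least 2-fold. The replicate numbers did not pair the arrays, since deviations of same-numbered arrays correlated at 0.03, −0.05, −0.16, 0.10 and −0.18. The replicate block gave 1069 rises, 370 falls and 98 falls of at least 2-fold, and gas-1 was at 0.67 with limma adjusted p = 0.0517. Without probe sets marked as sharing probes, 983 rose, 531 fell and 100 fell at least 2-fold, with fewer probe sets tested. Both gas-1 probe sets were left out there, so that setting does not test gas-1. With an estimated correlation 0 lists were called higher and 0 lower. Without wild-type replicates 1 and 5, 1529 fell, 341 at least 2-fold. Without mutant replicates 4 and 5, 262 fell at least 2-fold, 5 lists were lower and the collagen median was −0.027, against 0.22. Without all 4, 2317 rose and 2522 fell, 403 and 484 at least 2-fold, 8 lists were higher and 5 lower (7 of the 16 calls held and 6 were new), and medians were −2.64 for sperm genes, against −1.70, −0.022 for collagens, −0.092 for muscle, 0.16 for oocyte genes and −0.26 for the intestine. With the sperm mean as a covariate 3081 rose, 990 at least 2-fold and 107 fell at least 2-fold, 14 of the 16 list calls held and 6 were new, and medians were 0.79 for collagens, 0.85 for muscle, 0.49 for the intestine, 0.83 for peroxisomal oxidation, 0.33 for neurons, 0.28 for the vacuolar ATPase, −0.20 for oocyte genes and −0.46 for vitellogenins. Array weights held 11 of the 16 list calls. The gas-1 difference was 0.46 without all 4 arrays, 0.52 without mutant replicates 4 and 5, and 0.60 without wild-type replicates 1 and 5. It was 0.555 with array weights and 0.996 with the sperm mean as a covariate. The gas-1 call held in each of these fits, with a limma adjusted p of at most 0.0314. The cause of these shifts was not tested. The sperm mean itself differed between groups (−1.44), so as a covariate it is partly confounded with genotype.

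Leaving out single arrays gave 1176 to 1868 rises and 479 to 1609 falls, 388 to 500 rises and 93 to 371 falls of at least 2-fold, 10 to 14 lists higher and 2 to 5 lower, and a gas-1 difference of 0.59 to 0.72 that passed each time. Of the 2665 calls, 1652 to 2455 were shared with these fits, fewest without wild-type replicate 4. Quantile normalization gave 1561 rises and 1315 falls, with 35 of 37 lists on their side of the threshold. Of the 94 single genes named besides gas-1, 28 lost their call under the replicate block, 19 without mutant replicates 4 and 5, 5 to 16 without single arrays, 8 under centring and 3 under quantile normalization, and 0 changed direction in any fit.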

Other observations

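The tests in this part were chosen after the values were seen, and so were the genes named. Transcripts encoded by mitochondrial DNA were also higher in the mutant. All 8 measured transcripts had a positive difference, and ATP6 (0.27, SE 0.06), ND1 (0.24, SE 0.07) and CYTB (0.23, SE 0.06) rose (limma adjusted p = 0.0134, 0.0456 and 0.0472). Their mean was 11.69 ± 0.08 in the mutant and 11.49 ± 0.03 in the wild type (SD, n = 5), a difference of 0.20 (exact permutation p = 0.00794), in the same direction as the nuclear respiratory genes. These transcripts come from polycistronic precursors, so 8 of them are not 8 independent changes.

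Genes were also grouped by name prefix, with 165 families of at least 10 genes tested for rises and for falls (Fisher's exact test, adjusted over the 165 families per direction). Nuclear hormone receptors were enriched among rises, with 40 of 254 that rose, or 15.7%, against 7.42% of other genes (adjusted p = 0.000575). The receptor genes nhr-61 (3.03, SE 0.16, 8.18-fold) and nhr-210 (1.82, SE 0.10, 3.53-fold) were among them. The wild-type mean of nhr-210 (4.91) was below the background control median of wild-type replicate 1 (5.25) only, so its fold may be a lower bound. Of 12 bZIP transcription factor genes of the zip family 6 rose (adjusted p = 0.00374), zip-2 most (0.92, SE 0.13). The cyp, gst and ugt families were enriched among rises too (adjusted p = 0.00126, 0.000107 and 0.00261). Among falls the enriched families were ugt (11 of 64, adjusted p = 0.00919), lys (4 of 10, adjusted p = 0.0367), the RNA polymerase II subunits rpb (5 of 10, adjusted p = 0.00603) and the secretory pathway genes sec (5 of 19, adjusted p = 0.0498). Genes of a family are not independent, so these values overstate the evidence.

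The p38 kinase genes pmk-1 (1.62, SE 0.11, 3.08-fold), pmk-2 (2.27, SE 0.12, 4.81-fold) and pmk-3 (2.40, SE 0.08, 5.27-fold), which lie together in an operon, all rose, and the tubulin gene tbb-6 rose 9.70-fold (3.28, SE 0.20). Other single genes that rose were rips-1 at 7.92-fold (2.99, SE 0.23) and the sulfide oxidoreductase gene sqrd-1 at 4.56-fold (2.19, SE 0.31). The alcohol dehydrogenase gene adh-1 rose 12.8-fold (3.68, SE 0.20). The stress factor gene skn-1 rose 1.27-fold (0.34, SE 0.06), while the mitochondrial chaperone genes hsp-6 (0.22, SE 0.18, adjusted p = 0.518) and hsp-60 (0.30, SE 0.13, adjusted p = 0.183) did not pass.

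A smaller germline would be predicted to raise the share of X chromosome genes among rises, since the germline largely silences that chromosome. The share was 7.18% of 2355 genes on X against 7.59% elsewhere (Fisher's exact p = 0.501), which gives no sign of such an excess. Around gas-1, 9 of the 60 nearest measured genes changed, or 15%, against 10.9% of the other genes on X (Fisher's exact p = 0.295), which was the first version of the test of linked strain variants.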
